A study of Solanum lycopersicum with 84 samples.

How the data were processed

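Messenger RNA was profiled by sequencing in tomato (Solanum lycopersicum, cultivar Micro-Tom), in explants cut from cotyledons of 6-day-old seedlings and in the callus that formed on them. Per the labels' protocols, the explants were kept on shoot induction medium with 1 mg/L zeatin, a cytokinin, and 0.1 mg/L indole-3-acetic acid, an auxin. Libraries were made with an mRNA-seq kit and read as paired ends on either of a pair of platforms, and which library ran on which platform is not given in the sources used here. The labels list 84 libraries, of which 69 were analysed here. These were a time course at days 0, 1, 2, 4, 6, 8, 10, 12, 14 and 16 (30 libraries), mock and Torin2 callus at days 9, 10, 12, 14 and 16 (30 libraries), and callus labelled CK, EPFL8 and epfl8-mutant (9 libraries). Each group held 3 libraries, which the series' design text calls independent biological replicates. The 15 libraries labelled days 11, 13 and 15, dcl2 and pi-2 were not analysed here, so the planned comparisons of dcl2 and pi-2 callus with day 16 were not made.

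The deposited expression values were FPKM, fragments scaled by gene length and library total, in 3 tables of 34688 genes each, one table per experiment. Per the submitters' processing notes, the authors used FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.30.1. The genome build, the annotation release and the tool that gave the FPKM values are not given in the sources used here. The authors also deposited 3 tables of DESeq2 comparisons with a log2 fold change, a p-value and an adjusted p-value per gene. Those tables were used as one alternative to the tests described here and are named wherever they are quoted. No read counts were given, and the low FPKM values were not whole multiples of a common step, so the depth per library is unknown and no counting interval could be computed. FPKM divides by the total of each library, so a few abundant genes that change can shift all others. Each table was therefore also rescaled by the median ratio to the geometric mean of its libraries and to a total of 1000000 per library (TPM scale). Tests were made only within a table, since the tables were normalized separately.

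Column names of the Torin2 table for days 10, 12, 14 and 16 lacked the word Torin2 and matched names of time course libraries. They were assigned to the Torin2 groups because the table otherwise held mock libraries and a day 9 group that exists with Torin2 alone. The replicate numbers in these column names were not used. Genes were identified as in the files, which do not pair identifiers with gene names, and the RefSeq gene table given for tomato (assembly SLM_r2.1) held 0 of these identifiers. For this reason the 28 lists of gene names fixed before the data were examined matched 0 genes and gave no result, as did a list of 26 identifiers whose names could not be checked against the files. At most 2 identifiers that rose and 2 that fell are named per comparison. The rule fixed before the data were examined allowed more identifiers and asked for an informative gene description, which the files do not hold. The rule used was a shortened form of it. It took the largest changes among genes past both thresholds with a group mean of at least 5 FPKM and no overlap between the libraries of both groups. Exceptions are named as chosen after their values were seen.

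Values were transformed to log2(FPKM + 1), which understates changes of genes near 0. Genes with at least 1 FPKM in at least 3 libraries of a table were tested, which left 20486 genes in the time course, 18824 in the CK table and 19762 in the Torin2 table. Linear models with one mean per group were fitted across all groups of a table with limma 3.58.1 in R 4.3.3, with moderated variances that follow mean expression. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 change at least 1 in size. Change over any day, and Torin2 effects that differed between days, were tested with limma's moderated F test and a range of at least 1 among the group means or the 5 effects. The p-values measure the spread between libraries of one group, which was small, so nearly all weight in a call lay on the fold threshold. Whether libraries so close came from separate or from pooled tissue cannot be read from the files, and if tissue was pooled the SEs and p-values understate the spread between explants.

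Gene groups were then taken from one table and tested in another, a step chosen after the data were seen. They were the genes called higher or lower in the 4 steps of the time course, against CK, and in the mean Torin2 effect. Limma's camera test compared each group with the other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted within each comparison. A score per library was the mean log2 value of the genes that rose in a step minus that of the genes that fell. Scores were compared with exact permutation tests within a day, which cannot go below p = 0.1 with 3 libraries against 3, and with 100000 permutations within days over all 5 days. All tests were two-sided. Alternatives were the smaller pseudocount of 0.1 FPKM, no filter, both rescalings, robust variances, fits with the replicate number or with the compared groups alone, adjusted p without the fold threshold, each library left out in turn, and the authors' deposited tables. Count models were not run because no counts were at hand.

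The tests were tried on simulated data with the real genes and spreads and 200 of the more abundant genes changed by known folds. In the simulated day 1 against day 0 comparison (20486 genes), all 50 genes changed 3-fold and all 50 changed 4-fold were called, 20 of 50 changed 2-fold and 0 of 50 changed 1.5-fold, with 0 false calls. In the simulated EPFL8 against CK comparison (18824 genes) 12 of 50 genes changed 2-fold were called, with 3 false calls. In the simulated Torin2 day 9 comparison (19762 genes) 8 of 50 were called, with 1 false call. Both of these also called all 50 genes at 3-fold and at 4-fold and 0 of 50 at 1.5-fold. The counts of called genes thus leave out most changes of 2-fold or less. Genes near the filter of 1 FPKM were not among the changed ones, so larger changes of such genes can be missed too. Figures were drawn with matplotlib 3.10.9.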

Results

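Transcript levels were measured in tomato cotyledon explants and in the callus they formed on shoot induction medium, a route by which shoots regenerate from cut tissue. A time course of 10 days between 0 and 16, a Torin2 and mock series at 5 days, and a set of CK, EPFL8 and epfl8-mutant callus were compared, with 3 libraries in each group. Between 17190 and 19149 genes per library reached 1 FPKM in the time course, 18807 to 19010 in the Torin2 series and 17448 to 18375 in the CK set. Libraries of one group lay close together, with root mean square deviations from their group means of 0.07 to 0.15 log2 units in the time course, 0.07 to 0.10 in the Torin2 series and 0.10 to 0.18 in the CK set. The highest time course value belonged to replicate 3 of day 12.

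**Figure D1:**
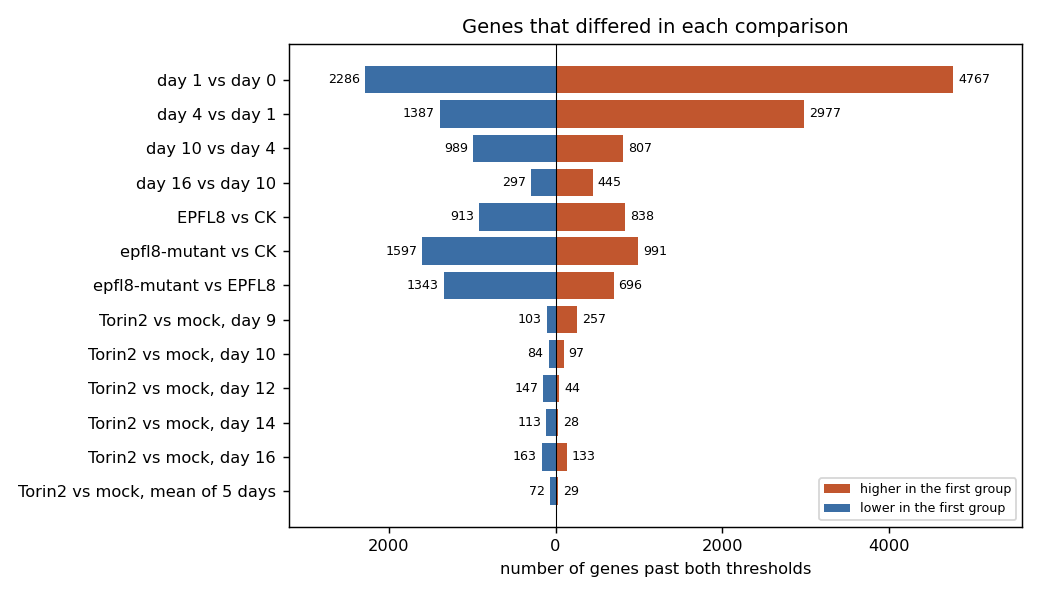
Number of genes past both thresholds (adjusted p and a log2 change of at least 1, limma) in each comparison of groups of 3 libraries, with genes higher in the first group to the right of 0 and genes lower to the left. The day 1 against day 0 bar reached 4767 and 2286 genes, and the mean Torin2 effect over 5 days 29 and 72.

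The time course followed the explant from day 0 to day 16 on shoot induction medium. The first day on the medium brought the widest change of the 4 steps tested: 7053 of 20486 genes differed between day 0, the cotyledon itself, and day 1, with 4767 higher and 2286 lower. Solyc02g062460.4 rose from 0.543 ± 0.169 FPKM on day 0 to 367 ± 10.1 on day 1 (SD, n = 3; log2 change 7.90 ± 0.08 SE, limma adjusted p = 3.03e-32). Solyc09g092110.5 fell from 1618 ± 87.9 to 2.96 ± 0.206 FPKM (SD, n = 3; log2 change -8.68 ± 0.09 SE, limma adjusted p = 9.56e-33), and Solyc03g006490.3 fell from 592 ± 0.388 to 0.882 ± 0.0459 FPKM. The 10 most abundant genes held 13.1 ± 0.125% of all FPKM on day 0 and 5.10 ± 0.0742% on day 1 (SD, n = 3). The deposited scale placed the median of all genes 0.25 log2 units higher on day 1, and the share of higher genes among those called, 67.6%, became 47.1% after median-ratio rescaling, which put that median at -0.07.

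Much of the day 1 response was still in place at the end of the time course. Of the 4767 genes higher on day 1, 3647 (76.5%) were also called higher on day 16 than on day 0, 37 were called lower and 1083 did not pass. Of the 2286 genes lower on day 1, 1179 (51.6%) were also called lower on day 16, 132 were called higher and 975 did not pass. Among all 20486 tested genes, 7946 were called higher and 2218 lower on day 16 than on day 0. On average the higher genes stood 1.85 ± 0.0064 log2 units above day 0 on day 1 and 1.64 ± 0.018 on day 16, and the lower genes at -1.87 ± 0.0096 and -1.14 ± 0.018 (SD, n = 3). Both comparisons share the day 0 libraries. In simulated genes that returned to their day 0 level, 0.0208% of the risers and 0% of the fallers would have passed the fold threshold on day 16. The simulation held only the small spread between libraries, so shares near 0 were set in advance. It left out the shift of all genes between the days, so it gives no expected share for genes that did not persist. The counts of genes called on both days moved with the scale, because the median of all genes lay 0.78 log2 units higher on day 16 than on day 0. After median-ratio rescaling, 1691 of 3368 genes higher on day 1 (50.2%) and 2335 of 3734 lower genes (62.5%) passed on both days. Which direction lasted more thus turned with the scale. The rescaled means went from 1.55 on day 1 to 0.95 on day 16 for the higher genes and from -2.34 to -1.94 for the lower genes.

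From day 1 to day 4, a further 4364 genes differed, 2977 higher and 1387 lower on day 4. Solyc04g007760.3 rose to 3243 ± 74.9 FPKM on day 4 (SD, n = 3; log2 change 8.67 ± 0.08 SE, limma adjusted p = 1.78e-33). Solyc02g070950.1 fell from 295 ± 5.79 to 3.69 ± 0.520 FPKM and Solyc02g070970.1 from 201 ± 3.05 to 3.59 ± 0.115 FPKM (SD, n = 3), with log2 changes of -5.99 and -5.46. The genes that rose in this step stood on average at -0.09 log2 units against day 0 on day 1, then 0.71 higher on day 2 and 1.64 higher on day 4, and were still 1.45 higher on day 16 (-0.41, 0.27, 1.08 and 0.78 after median-ratio rescaling). The median of all genes lay 0.26 log2 units higher on day 4, and the 68.2% share of higher genes became 48.5% after median-ratio rescaling.

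Between day 4 and day 10, 1796 genes differed, 807 higher and 989 lower on day 10. Without a fold threshold this balance turned, to 7813 and 6039. Solyc08g078940.1 rose from 0.129 ± 0.119 to 90.6 ± 4.48 FPKM and Solyc03g083998.1 from near 0 to 65.2 ± 3.74 FPKM (SD, n = 3), with log2 changes of 6.35 ± 0.07 and 5.91 ± 0.08 (SE; limma adjusted p = 9.47e-31 and 3.18e-28). Solyc06g006000.3 fell from 45.6 ± 0.964 to 0.172 ± 0.0379 FPKM. The 989 genes that fell in this step described a pulse: on average they stood 1.43 log2 units above day 0 on day 4, 0.66 on day 6 and -0.13 on day 10 (0.88, 0.10 and -0.71 after median-ratio rescaling).

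Between day 10 and day 16, 742 genes differed, 445 higher and 297 lower on day 16. Solyc06g006000.3 returned to 47.1 ± 2.55 FPKM on day 16, and Solyc06g051680.1 rose from 4.41 ± 0.426 to 146 ± 5.25 FPKM (SD, n = 3; log2 change 4.77 ± 0.06 SE, limma adjusted p = 1.18e-28). Solyc09g084450.3 fell from 54.5 ± 1.15 to 1.72 ± 0.286 FPKM. On average the 445 genes lay below the cotyledon from day 1 to day 10, at -0.92 log2 units on day 10, and at 0.59 ± 0.028 on day 16 (SD, n = 3). After median-ratio rescaling these values were -1.49 and -0.04, so the rise held and the end point above the cotyledon did not. The mock series held a second set of libraries of the same days. There, 403 of the 438 measured higher genes and 259 of the 283 measured lower genes moved the same way from day 10 to day 16, and 165 and 120 of them were called with the same direction, against 6 and 0 called with the opposite one. Across 19565 genes, which are not independent replicates, the log2 changes of both series correlated with r = 0.73.

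**Figure D2:**
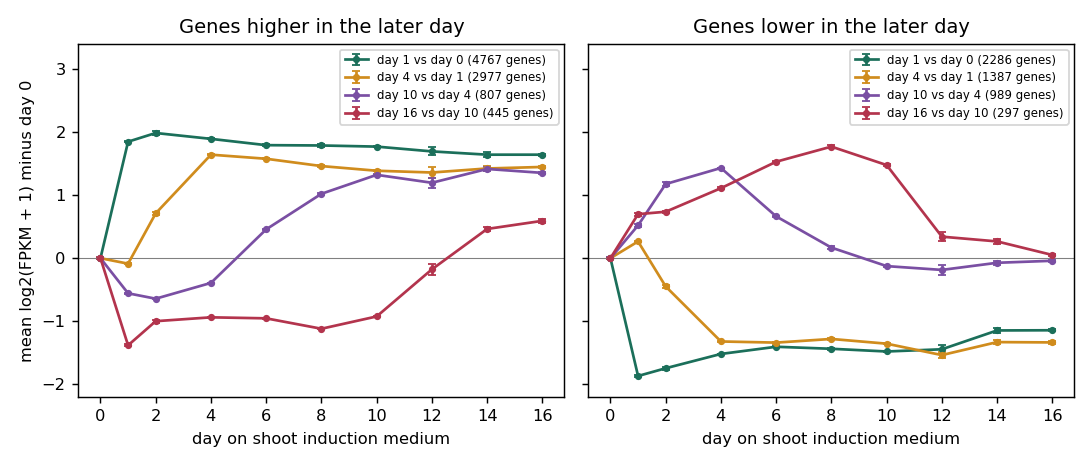
Mean log2(FPKM + 1) minus day 0 (vertical axis) over the days on shoot induction medium (horizontal axis) for genes called higher (left) or lower (right) in each of 4 steps; points are means and bars SDs of 3 libraries. The genes that rose in the first step stood at 1.85 on day 1 and 1.64 on day 16 (1.55 and 0.95 after median-ratio rescaling), and those that rose from day 10 to day 16 went from -0.92 to 0.59 (-1.49 to -0.04 after median-ratio rescaling).

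Over all 10 days, 15323 of the 20486 tested genes varied with a range of at least 1 log2 unit (moderated F test of limma). Their highest day was most often day 0 (2627 genes, 17.1%), day 16 (2531 genes, 16.5%), day 4 (1907 genes) or day 1 (1889 genes). Their lowest day was day 0 for 8620 genes (56.3%). After median-ratio rescaling the order changed: 3882 of the same genes peaked on day 0, 2897 on day 1, 1704 on day 4 and 1509 on day 16, and 6599 (43.1%) were lowest on day 0.

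The second set compared callus labelled CK, EPFL8 and epfl8-mutant. EPFL genes encode small secreted cysteine-rich signalling peptides, and the design text describes the mutant as a knockout of EPFL8. The labels give no day for these libraries and do not say how CK and EPFL8 callus differ, and the targeted gene could not be looked up because the files hold no gene names. All 3 groups lay apart, with 53.0% and 38.4% of the variance on the leading principal components. Between epfl8-mutant and CK callus 2588 of 18824 genes differed, 991 higher and 1597 lower in the mutant. Without a fold threshold 6882 were higher and 5142 lower. Solyc03g083998.1, which appeared in the time course between days 4 and 10, stood at 218 ± 15.5 FPKM in the mutant and 4.48 ± 1.51 in CK (SD, n = 3; log2 difference 5.35 ± 0.21 SE, limma adjusted p = 2.44e-09). Solyc06g050870.3 stood at 0.130 ± 0.0332 FPKM in the mutant and 293 ± 43.5 in CK (log2 difference -8.01 ± 0.10 SE, limma adjusted p = 1.49e-12).

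Between EPFL8 and CK callus 1751 genes differed, 838 higher and 913 lower in EPFL8. Solyc07g041320.3 was near 0 in CK (0.0609 ± 0.0582 FPKM) and high in both EPFL8 (92.3 ± 4.82) and mutant callus (106 ± 1.42; SD, n = 3). Solyc08g077910.3 stood at 4.02 ± 1.59 FPKM in EPFL8 and 151 ± 24.5 in CK. The direction of this comparison depended on the scale and the thresholds. Without a fold threshold 9422 genes were higher and 3486 lower. Of the called genes 47.9% were higher in EPFL8, against 23.9% after median-ratio rescaling, 67.8% on the TPM scale and 62.3% in the authors' deposited table, and the deposited values put the median of all genes 0.22 log2 units higher in EPFL8.

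Between epfl8-mutant and EPFL8 callus 2039 genes differed, 696 higher and 1343 lower in the mutant. Solyc01g067860.3 stood at 172 ± 31.4 FPKM in the mutant and 4.63 ± 1.86 in EPFL8, and Solyc07g044900.1 at 0.399 ± 0.303 and 394 ± 8.46 (SD, n = 3; log2 differences 4.97 ± 0.23 and -8.16 ± 0.13 SE, limma adjusted p = 1.52e-08 and 9.41e-12). Of the called genes 34.1% were higher in the mutant, and 47.7% after median-ratio rescaling, with the median of all genes at -0.15 before it.

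EPFL8 and mutant callus departed from CK partly in the same genes. Both were higher than CK in 240 genes and both lower in 603, where independent lists of these lengths would share 44.1 and 77.5, and in 90 genes they were called in opposite directions (76 higher in EPFL8 and lower in the mutant, 14 the reverse). Across genes the log2 differences correlated with r = 0.53, close to the 0.50 of simulated groups without any change, since both use the same CK libraries. Their covariance, 0.27, lay far above the simulated 0.0066. The simulation held only the spread between libraries, and independent lists share no reference group. A state peculiar to the CK libraries could thus give this covariance and overlap as well. The 3 CK libraries could not be split with at least 2 on each side, so the overlap was not tested on separate controls. After median-ratio rescaling, 141 genes were higher and 759 lower in both.

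Gene groups of the time course were read in this set with limma's camera test. In epfl8-mutant against CK callus, the genes that had fallen from day 1 to day 4 were lower: of 1218 measured, 303 were called lower and 29 higher, with a median log2 difference of -0.51 against 0.07 for all genes (adjusted p = 3.33e-23, and adjusted p = 0.0208 with an estimated correlation). The genes that had risen from day 10 to day 16 were also lower in the mutant, with 169 of 406 called lower and 40 higher and a median of -0.72, but this group did not pass with an estimated correlation (adjusted p = 0.132). Against EPFL8 callus, 173 of the same 406 genes were called lower in the mutant and 26 higher (adjusted p = 2.02e-06, and adjusted p = 0.253 with an estimated correlation). The score of that step, genes that rose minus genes that fell, was -0.58 ± 0.01 in the mutant, 0.19 ± 0.04 in CK and 0.40 ± 0.06 in EPFL8 (SD, n = 3; -0.24, 0.20 and 0.70 with the median over genes), with no overlap between mutant and CK libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow). The last step was not alone in this. Mutant minus CK was -0.77 for its score, 0.78 for that of the day 1 to day 4 step and 0.59 for the first step. For the day 4 to day 10 step it was 0.06. In EPFL8 against CK callus no time course group passed with an estimated correlation (smallest adjusted p = 0.257).

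Torin2, an ATP-competitive inhibitor of the TOR kinase that the submitters list as an autophagy inhibitor, was applied at 1 µM and compared with mock on each of 5 days. Past both thresholds, Torin2 changed fewer genes on each day than any step of the time course. The counts were 360 of 19762 on day 9 (257 higher, 103 lower), 181 on day 10 (97 and 84) and 191 on day 12 (44 and 147). On day 14 they were 141 (28 and 113) and on day 16 296 (133 and 163). Without a fold threshold this ranking did not hold, with 12741 genes for Torin2 on day 9 and 12654 for day 16 against day 10. In the authors' deposited table the day 10 balance turned, with 373 higher and 459 lower, and the day 14 split was 185 and 423. On day 9 Solyc07g066360.1 stood at 38.2 ± 4.44 FPKM with Torin2 and 2.08 ± 0.0246 in mock, and Solyc10g086100.2 at 31.5 ± 0.292 and 1.89 ± 0.128 (SD, n = 3; log2 differences 3.66 ± 0.08 and 3.49 ± 0.09 SE, limma adjusted p = 5.34e-25 and 2.19e-23). On day 16 Solyc03g078570.3 stood at 65.8 ± 2.98 FPKM with Torin2 and 3.25 ± 0.131 in mock, and Solyc12g006680.2 at 1.05 ± 0.193 and 28.7 ± 1.34.

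Few genes responded to Torin2 on every day. Averaged over the 5 days, 101 genes differed, 29 higher and 72 lower. That balance belongs to changes of at least 2-fold. Without a fold threshold 8263 genes were higher and 6194 lower. The balance also turned on day 12 (5117 and 4407) and day 14 (4810 and 3733). Of the 329 genes called lower on any day, 18 were lower on all 5 days, and of the 429 called higher on any day, 1 was higher on all 5. Solyc03g083998.1 averaged 0.991 ± 0.638 FPKM with Torin2 and 28.5 ± 11.9 in mock, and Solyc01g067860.3 averaged 4.16 ± 0.716 and 48.4 ± 11.9 (SD over days and libraries, n = 15; log2 differences -3.79 ± 0.05 and -3.23 ± 0.02 SE, limma adjusted p = 7.21e-31 and 2.15e-36). Both were among the genes lower on all 5 days. Solyc02g070110.1, the gene higher on all 5 days, averaged 15.0 ± 7.76 and 2.29 ± 0.497 FPKM, and its log2 difference went from 3.39 on day 9 to 1.29 on day 16. Effects of neighbouring days were alike and drifted apart with time: across genes, which are not independent replicates, r was 0.80 between days 9 and 10 and 0.24 between days 9 and 16, each from separate libraries.

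**Figure D3:**
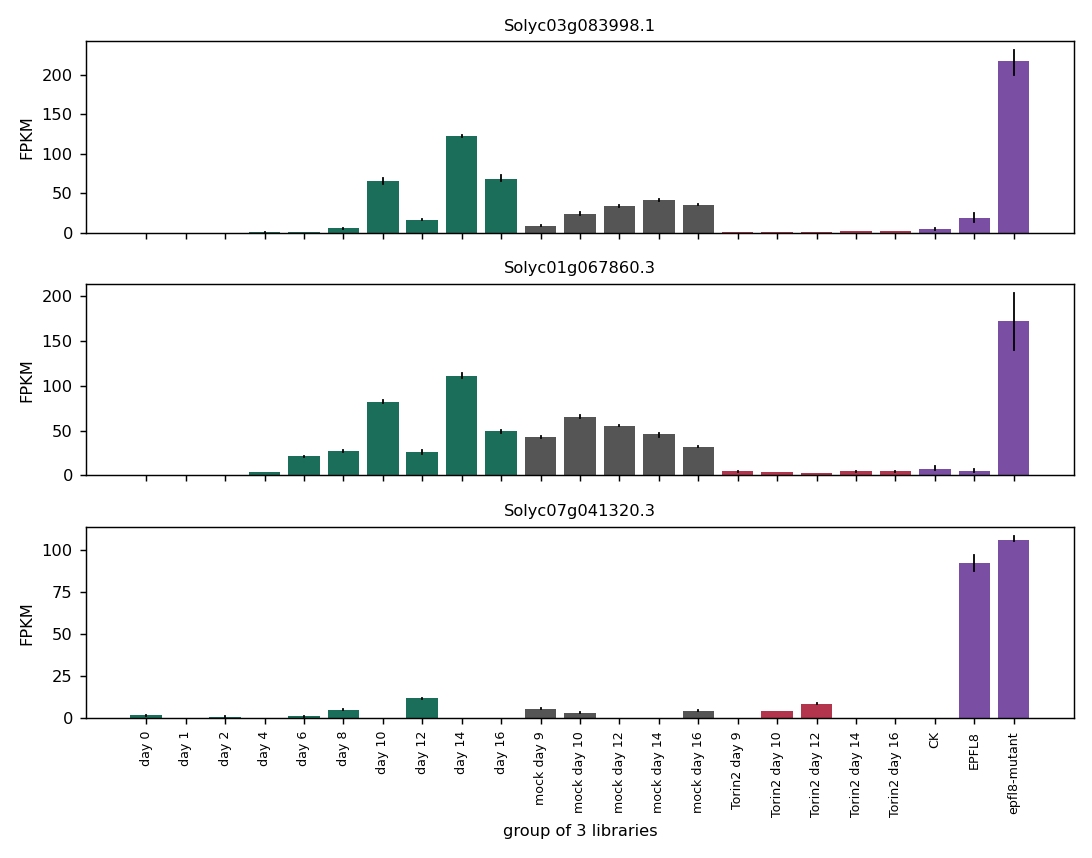
FPKM of 3 genes, chosen after their values were seen because they recur across experiments, in each group of the time course (green), mock (grey), Torin2 (red) and CK set (purple); bars are means and black lines the range of 3 libraries, and levels across the experiments come from separately normalized tables. Solyc03g083998.1 reached 41.1 FPKM in mock and 1.69 with Torin2 on day 14, and 218 in epfl8-mutant callus.

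The genes that Torin2 lowered were largely genes that rise during callus growth. Of the 72 genes lower over the 5 days, 47 had risen from day 4 to day 10 of the time course and 0 had fallen, with a median log2 change of 1.83 in that step against 0.05 for all genes (limma camera adjusted p = 3.36e-22, and adjusted p = 0.000621 with an estimated correlation). Read the other way, the 798 measured genes that rose from day 4 to day 10 held 44, 43, 98, 79 and 87 genes called lower with Torin2 on days 9, 10, 12, 14 and 16, and 23, 17, 11, 10 and 16 called higher. This group was lower on each day (adjusted p = 0.0169, 0.00423, 0.00103, 0.000665 and 0.0193 with an estimated correlation, limma camera). The 890 measured genes that fell from day 4 to day 10 were higher over the 5 days, by a median of 0.16 log2 units against 0.02 for all genes (adjusted p = 8.44e-07, and adjusted p = 0.00797 with an estimated correlation). On day 9 alone this second group did not pass with an estimated correlation (adjusted p = 0.0967).

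The score of the day 4 to day 10 step, genes that rose minus genes that fell, was lower with Torin2 on all 5 days, by 0.33 on day 9, 0.38 on day 10, 0.49 on day 12, 0.43 on day 14 and 0.33 on day 16, while the score rose by 0.76 in mock from day 9 to day 16. The mean difference of -0.39 gave p = 1e-05, the smallest that 100000 permutations within days can give (adjusted p = 1.33e-05 over the 4 steps). The first step was lower with Torin2 by 0.10 and the day 1 to day 4 step higher by 0.05 on average, both with p = 1e-05 in the permutation test, and the second mean rested mostly on day 16 (0.13, against 0.03 to 0.04 on the other days). The gene groups of these steps did not pass for the mean Torin2 effect with an estimated correlation (limma camera adjusted p = 0.152 for both groups of the first step, 0.29 and 0.907 for those that rose and fell from day 1 to day 4). The score of the last step, day 10 to day 16, had no common direction (mean difference 0.07, permutation p = 0.304).

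Instead, the last step crossed over. On day 9 its score was -0.79 ± 0.0041 with Torin2 and -1.35 ± 0.013 in mock, a difference of 0.56, and on day 10 the difference was 0.40 (SD, n = 3). On days 12 and 14 the score was lower with Torin2 by 0.14 (by 0.33 and 0.23 when the median over genes was taken), and on day 16 it was 0.38 ± 0.0057 with Torin2 and 0.70 ± 0.0019 in mock, a difference of -0.32. The difference on day 9 exceeded that on day 16 by 0.88 (exact permutation p = 0.005 over 400 arrangements within days, the smallest possible). These arrangements also break up the effect of Torin2 within each day. Their p therefore cannot decide whether the effects of both days were equal. On day 9, 32 of the 438 measured genes that rose in the last step were called higher with Torin2 and 9 lower, and 32 of the 283 that fell were called lower and 2 higher (adjusted p = 0.0169 and 0.00104 with an estimated correlation, limma camera). On day 16, 62 of the 438 were called lower and 22 higher (adjusted p = 0.0321 with an estimated correlation).

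**Figure D4:**
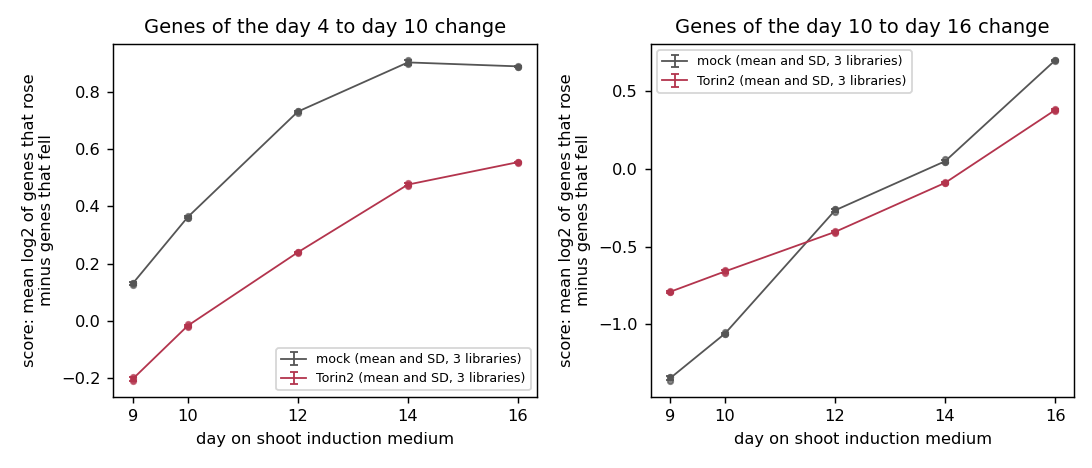
Score per library (mean log2 of genes that rose in a time course step minus that of genes that fell) in mock (grey) and Torin2 callus (red) by day, for the day 4 to day 10 step (left) and the day 10 to day 16 step (right); lines join the means of 3 libraries and bars are SDs. The left score was lower with Torin2 on all 5 days, and the right score went from 0.56 above mock on day 9 to 0.32 below it on day 16.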

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

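The tests of scaling and of a uniform delay were chosen after the results were seen. The Torin2 effect differed between days for 771 genes (moderated F test of limma, range of the 5 effects at least 1 log2 unit). Besides, 14 of the 744 genes called on any day were called higher with Torin2 on one day and lower on another. The score of the day 10 to day 16 genes showed the same kind of difference, with an effect on day 9 that lay 0.88 above that on day 16.

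In callus on Torin2 the score of the last step of the time course lay above mock on day 9 and below it on day 16. A shift of the authors' scaling would move the genes that rise and those that fall the same way, but on day 9 the falling genes lay at -0.31 and the rising ones at 0.25 relative to mock. The day 9 score, 0.56 above mock, cannot by itself decide on a uniform delay of the callus by Torin2. In the time course this score fell before it rose. From day 4 to day 8 the rising genes went from -0.94 to -1.12 log2 units against day 0. The falling genes went from 1.11 to 1.77. Callus held back to an earlier day could thus also score above mock. Libraries of another age in the Torin2 day 9 group stay open: at least 360 genes separated it from each mock day and at most 65 separated neighbouring mock days, but Torin2 separated the other days by 141 to 296 genes, so libraries of any age would have passed. Another candidate explanation that stays open is an effect of Torin2 itself that lowers the genes of the day 4 to day 10 step throughout and flattens the course of the last step; it was found and tested on the same data, and nothing here tests when or how long Torin2 was present.

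In 3 of 100 splits within days, the real one included, at least 771 genes, the real count, had effects that differed between days. These splits also break up the mean effect of Torin2, so their share cannot decide whether its effects differ between days. The highest other split gave 1169 genes, and the 2 drawn splits with as many genes each kept or exchanged the labels of whole groups on at least 3 of the 5 days, whereas no other split did so on more than 2 days. Such splits turn the mean effect of Torin2 into a difference between days, which is a structure of the samples. For the mean effect, 1 of 100 splits, the real one with 101 genes, gave as many, and the highest other gave 17. For change over any day, 1 of 100 splits gave as many as the real 15323 genes, and the highest other gave 4446. The comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. In the 4 time course steps the real splits called 7053, 4364, 1796 and 742 genes and the other splits 0. For Torin2 on days 9, 10, 12, 14 and 16 they called 360, 181, 191, 141 and 296, and the others 0. For EPFL8 against CK, the mutant against CK and the mutant against EPFL8 they called 1751, 2588 and 2039, and the highest other split in each gave 1. Thus 1 of 10 splits, the real one, had the largest count in all 12 comparisons. Every other split mixes libraries of both groups, which moves their difference into the spread. Low counts there were largely set in advance and cannot decide on a cause.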

How the results depend on the processing

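Fits without day 12, the Torin2 day 9 fit with the replicate number, and all settings of gene groups, scores and levels against day 0 were added after seeing the data. The 15 counts of genes stayed within 1.5 times of the reported ones without the filter, on the TPM scale, after median-ratio rescaling and with robust variances, as did the 12 counts run with the compared groups alone, the 5 run without day 12 and 162 fits that left out 1 library. Those fits gave 7055 to 7078, 4350 to 4391, 1768 to 1808 and 735 to 754 genes in the time course steps, 15304 to 15382 over any day, 1695 to 1817 for EPFL8 against CK, 2548 to 2611 and 1954 to 2097 for the mutant against CK and EPFL8, 358 to 368, 182 to 192, 194 to 207, 139 to 145 and 294 to 305 for the Torin2 days, 97 to 103 for the mean effect and 767 to 793 for effects that differed between days. Adjusted p without a fold threshold called 17915 genes for day 1 against day 0, 17392 for day 4 against day 1, 13852 for day 10 against day 4, 12654 for day 16 against day 10, 12908 for EPFL8 against CK, 12024 and 12199 for the mutant against CK and EPFL8, 12741, 10823, 9524, 8543 and 8855 for Torin2 on days 9, 10, 12, 14 and 16, 14457 for its mean effect and 11787 for effects that differed between days. This follows from the setting, which adds small changes between libraries with little spread. A pseudocount of 0.1 FPKM, which widens the changes of low genes, gave 2776 for day 10 against day 4, 1397 for day 16 against day 10, 2779 for EPFL8 against CK, 629, 449, 446, 337 and 592 for the Torin2 days, 295 for the mean effect and 1374 for effects that differed between days. The authors' deposited table held 7298, 3697 and 1983 for the last 3 time course steps, 3804, 4540 and 4198 for the comparisons of EPFL8 with CK and of the mutant with CK and EPFL8, and 1018, 832, 810, 608 and 1119 for the Torin2 days; the cause was not tested. It held from 96.1% to 99.9% of the genes called here with the same sign. The 32 identifiers chosen by the rule for the largest changes, in 52 pairs with a comparison, kept their direction and call in each setting run.

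Same-numbered libraries did not deviate together (mean correlation of deviations 0.016, from -0.24 to 0.22, in the time course and 0.0042, from -0.14 to 0.08, in the CK set). A replicate block gave 7054, 4364, 1796 and 742 genes in the time course steps, 15322 over any day, 1752, 2588 and 2040 in the CK set and 362 for Torin2 on day 9. It was not run on the other Torin2 days, whose replicate numbers were not used. Of 126 tests of gene groups, 58 lost their call with an estimated correlation, 5 lost and 3 gained it after median-ratio rescaling, 1 lost it with the smaller pseudocount and 0 turned; with 1 library left out, 1034 tests kept their result, 5 lost the call and 5 gained it. Of 20 score differences between Torin2 and mock, 17 moved by at least the SD of their libraries and kept their sign with the median over genes, 2 stayed and 1 turned sign: the day 1 to day 4 score on day 14 went to -0.0083 with the median over genes, where the cause was not tested. Without the most abundant 1 percent of genes 3 moved and 17 stayed. Not run were count models, the authors' table for the mean effect and F tests, fits of the compared groups alone for these, and the dcl2 and pi-2 comparisons. The unknown depth limits what can be said of genes near 0.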

Other observations

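The tests of scaling in the CK set were chosen after the result was seen. Some genes of the early Torin2 response also separated EPFL8 and mutant callus from CK. Of the 854 measured genes lower in EPFL8 than in CK, 110 were called higher with Torin2 on day 9 and 19 lower, with a median log2 difference of 0.25 against 0.06 for all genes (limma camera adjusted p = 0.000205, and adjusted p = 0.0773 with an estimated correlation). On day 14 the same group held 6 genes called higher and 38 called lower and did not pass (adjusted p = 0.653). Of the 1478 measured genes lower in the mutant than in CK, 119 were called higher with Torin2 on day 9 and 15 lower, and on day 16 these counts were 10 and 76. This group did not pass on day 9 with an estimated correlation (adjusted p = 0.00136, and adjusted p = 0.0773 with it), nor on day 16 either way (adjusted p = 0.243 and 0.561, limma camera).

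Solyc07g041320.3, chosen after its values were seen, went on and off between groups while libraries of a group stayed together. It stood at 5.79 ± 0.436 and 3.30 ± 0.267 FPKM in mock on days 9 and 10 (SD, n = 3), was listed at 0 in all 3 mock libraries of day 12, and stood at 4.65 ± 0.463 in mock on day 16; with Torin2 it stood at 8.49 ± 0.411 on day 12 and was listed at 0 in all libraries of days 9, 14 and 16. In the time course, 24 genes went at least 2 times between at most 0.1 and at least 3 FPKM in all libraries of a day, and in 0 of their groups did libraries of one day fall on both sides. On the other hand 3 such genes among the Torin2 groups had 3 groups with libraries on both sides.

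By rank correlation over 19565 genes, mock callus of days 10, 12 and 14 resembled day 12 of the time course most. The same held for Torin2 callus of days 9, 10, 12 and 14. Mock callus of day 9 resembled day 10 most, with rho of 0.9852. For Torin2 callus of day 9, rho was 0.9745 with day 12 and 0.9647 with day 10. Mock and Torin2 callus of day 16 resembled day 16 most, with rho of 0.993 and 0.983. The CK set resembled the time course less: rho was at most 0.837 for CK (day 14), 0.906 for EPFL8 (day 12) and 0.891 for the mutant (day 12), across separately normalized tables and 18587 genes.

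Past both thresholds, between 1751 and 2588 genes separated CK, EPFL8 and mutant callus pairwise, many more than Torin2 changed on any day. Without a fold threshold 12024 to 12908 genes separated them, against 12741 for Torin2 on day 9. Scaling or a few abundant genes as the whole cause is argued against by the 2642 genes still called between mutant and CK callus after median-ratio rescaling. A difference in callus age within days 0 to 16 stays open. Of the genes called between mutant and CK, 7.24% did not vary over the time course, against 25.1% of all genes tested in both. These shares cannot decide on age, because genes past a fold threshold in any comparison may be the more variable ones whatever the cause. Age and genotype cannot be told apart here because the labels give no day for these libraries. An effect of EPFL8 itself stays open and untested.

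Day 12 of the time course stood off the line between days 10 and 14 in 43 genes (3 to 255 genes on the other inner days), 41 of them below it, while 0 genes did so on day 12 in mock callus. Replicate 3 of day 12, the library farthest from its group, does not account for this, since 38 of the genes were left without it. Neither does scaling, with 38 left after median-ratio rescaling. A change that belongs to day 12 of culture is argued against by the mock series, where 55.8% of the 43 genes lay on the same side of the line, near the 50 percent of chance, with a median deviation of 0.22 log2 units against 1.66. A condition of the day 12 cultures that the labels do not name stays open. Solyc03g083998.1 stood at 16.4 ± 0.813 FPKM on day 12 between 65.2 and 123 on days 10 and 14. Solyc01g067860.3 stood at 26.4 ± 2.19 between 82.1 and 111. Of the 41 genes below the line, 4 were lower in the mean Torin2 effect, where independent lists would share 0.151. Of 39 measured in the CK set, 11 were higher and 17 lower in the mutant than in CK (2.02 and 3.23 for independent lists). Variable genes may recur in such lists whatever the cause.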
